A study of Mus musculus with 6 samples.

How the data were processed

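RNA sequencing was carried out on 6 libraries of E0771 mouse breast cancer cells, 2 treated with DMSO, 2 with Enniatin A (EnnA, 7.4 µM, 24 h) and 2 with 17-AAG (0.5 µM, 24 h) after 48 h of growth, per the labels. For DMSO the labels give the 48 h of growth but no treatment time. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome mm9 and expression was compared with Cufflinks and Cuffdiff. Versions of these tools are not given in the sources used here. The authors deposited 2 tables, EnnA against DMSO and 17-AAG against DMSO, each with 1 row per gene, the locus, a value for each group, a log2 fold change, a p-value and a q-value.

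Group values in the deposited tables were read as FPKM, the unit of Cuffdiff output, and are the authors' values pooled over 2 libraries. Fold changes in the deposited tables are log2 ratios of DMSO over compound, checked against the ratio of the FPKM columns where both were above 0 (0 genes of the EnnA table and 2 of the 17-AAG table differed by more than 0.1), and their sign was turned so that a positive value means higher with the compound. Genes listed at 0 with DMSO, 12 and 9, have no log2 value. The p-value in the deposited tables is the authors' Cuffdiff p, with a lowest value of 5e-05, and the q-value in the deposited tables equals the Benjamini-Hochberg adjustment of those p over all genes listed. The lowest q is 0.000207 in the EnnA table and 0.000453 in the 17-AAG table. Loci are given in mm9 as the authors' deposited tables list them, and whether a start counts from 0 or 1 is not stated. The tables list 11024 and 11305 genes, of which 10932 are in both. They were normalized separately: DMSO values in the 17-AAG table are 1.10 times those in the EnnA table at the median gene. Values per library, read counts and the test statistic were not used here.

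A gene was called higher or lower at q under 0.05. The standard error of a log2 change was taken as its size divided by the normal quantile of the authors' 2-sided p. The plan had assumed that a test statistic would be listed, and this replaced it. For the 2660 genes of the EnnA table and 1249 of the 17-AAG table at the lowest p, that error is an upper limit. The median implied error was 0.156 and 0.152 at 10 to 100 FPKM, and 0.366 and 0.344 under 2 FPKM. Depth per library is unknown, since the tables hold FPKM alone, so the precision that depth gives cannot be stated beyond these errors. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values speak for these libraries only. With pooled values, how far they reflect each gene's own spread between libraries could not be checked.

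The difference between the compounds was tested for 10922 genes as the EnnA log2 change minus the 17-AAG log2 change, by a z test with both implied errors and Benjamini-Hochberg adjustment. The errors were combined as if independent although the DMSO libraries were shared, which makes this test conservative. It rests on a normal approximation, which 2 libraries per group and pooled values cannot replace with an exact test, so single-gene differences are given without p. Tested on simulated data, with 50 genes each changed 1.5, 2, 4 and 8-fold among 10922, it recovered 6, 28, 62 and 74% of them and called 0 of 10722 unchanged genes. The simulated noise was drawn from the same implied errors, so it cannot show whether those errors are right. Far fewer genes were changed there than were called in the data (4169), so these rates may not carry over. Overlap was set against the product of the shares called in each table. Correlation was set against 100 simulated pairs of tables with no effect and a shared DMSO error.

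Before the data were examined, 41 gene lists were written, of which 40 had at least 1 listed gene. Of the 41 lists, 7 hold markers of cell types, among them luminal and basal mammary epithelium. Members called higher and members called lower were each compared with all listed genes by a 2-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 160 tests (80 for the difference). The median log2 change of a list was placed among 10000 random lists drawn from the same 10 bins of expression. Counts adjusted over the list alone used the authors' p for the members only. Lists share some members, so their results are not independent.

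Named genes followed a rule fixed beforehand: 22 genes given by name, the 10 genes with the largest change in each direction per comparison among called genes with at least 1 FPKM in each group and at least 5 FPKM in one of them, and up to 4 members per list. Genes in the lists of tubulins, S100 proteins, iron, snoRNA hosts and decay factors, and genes singled out as examples of shared change, were chosen after their values were seen. Genes that share a locus with another listed gene (1203 and 1280) or have near-identical copies are marked as uncertain where they are named.

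Alternatives were a q under 0.01, a minimum 2-fold change, a minimum of 1 FPKM, centring on the median of expressed genes, a pseudocount of 1 FPKM and errors inflated 1.5 times. Chosen after seeing the data were the removal of genes with shared loci and of small RNA genes, a lower limit on the errors, the removal of Mir546, and the subtraction of the median of genes of like transcript length and expression, also for the difference between compounds. Those genes included the list members themselves, so the subtraction can also remove part of a real change that they share. Transcript length and GC content came from the GENCODE vM21 annotation, which may not be the one the authors used, and no coordinate was taken from it. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Single values of some list members are not reported here. Reads were not aligned again, and splits of the samples were not counted because each group has 2 libraries and 1 pooled value.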

Results

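Messenger RNA was measured by RNA sequencing in E0771 cells, a mouse breast cancer line of C57BL/6 background, after exposure to 1 of 2 compounds or to the solvent DMSO. Enniatin A (EnnA) is a cyclic depsipeptide mycotoxin of Fusarium fungi that carries cations across membranes, and 17-AAG is a geldanamycin derivative that binds the ATP pocket of the chaperone HSP90. Cells grown for 48 h received EnnA at 7.4 µM or 17-AAG at 0.5 µM for 24 h, and each of the 3 groups had 2 libraries. The time of exposure to DMSO is not stated. The series concerns inhibitors of HSP90 and immune activation, so chaperone, stress and immune genes were fixed for description before the data were examined. The authors' deposited tables set each compound against DMSO and give 1 pooled FPKM value per gene and group. Values per library were not used here, so no standard deviation or n stands beside a pooled FPKM, and depth per library is unknown. The error given with a log2 change is the standard error implied by the authors' p, and for genes at the lowest p of 5e-05 it is an upper limit. A gene was called higher or lower when its q was under 0.05.

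EnnA raised genes of protein folding in the endoplasmic reticulum, of the integrated stress response and of ribosome production, and lowered genes of mitosis, DNA replication, sterol synthesis and extracellular matrix. Hspa5, which encodes the main Hsp70 chaperone of the endoplasmic reticulum, rose 4.51-fold, from 339.8 FPKM with DMSO to 1532 FPKM with EnnA (log2 change 2.17, implied SE at most 0.54). Ddit3, which encodes the stress transcription factor CHOP, rose 6.38-fold (log2 change 2.67, implied SE at most 0.66); it shares its locus with Mars, so the value is uncertain. Il23a, encoding a subunit of interleukin 23, rose 8.80-fold, while S100a4, a calcium-binding protein linked to cell motility, was 18.6-fold lower. At q under 0.05 in the authors' deposited table, 2675 of 11024 listed genes were higher and 2747 were lower with EnnA. This was 49.2% of the genes, and 6001 had an unadjusted p under 0.05.

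Of the 26 listed genes of the endoplasmic reticulum unfolded protein response, 23 rose and 0 fell (Fisher's exact test against all listed genes, adjusted p = 4.2e-10). Their median log2 change was 0.76, at percentile 100 among 10000 random lists of matched expression. Vimp, a selenoprotein of the membrane that exports misfolded proteins, rose 4.01-fold, the chaperone gene Hyou1 rose 3.05-fold and the secreted stress factor Manf rose 2.82-fold. Calr, encoding the lectin chaperone calreticulin, rose 2.49-fold. Of 30 listed genes of the integrated stress response, 25 rose and 1 fell (Fisher's exact adjusted p = 5.91e-10, median log2 change 0.93). Ppp1r15a, encoding a phosphatase subunit that reverses eIF2-alpha phosphorylation, rose 11.9-fold, and the transcription factor gene Atf3 rose 6.97-fold. The cationic amino acid transporter gene Slc7a3 rose 6.99-fold, and Atf4 rose with a log2 change of 0.84 (implied SE at most 0.21). In the mitochondrial unfolded protein response list, 7 of 14 genes rose and 1 fell, which did not pass the list test (Fisher's exact adjusted p = 0.163). Its risen members included the protease gene Lonp1 (log2 change 1.22) and the chaperone gene Hspa9 (1.08).

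Genes that make ribosomes rose together with EnnA. Of 27 ribosome biogenesis and MYC target genes, 20 rose and 0 fell (Fisher's exact adjusted p = 1.21e-06, median log2 change 0.53). Myc itself rose with a log2 change of 1.01 (implied SE at most 0.25), as did Nop58, a component of snoRNA particles (1.15), and the spermidine synthase gene Srm (1.13). Of 36 cytosolic ribosomal protein genes, 27 rose and 1 fell (Fisher's exact adjusted p = 6.29e-09). The median log2 change of the most abundant of 10 equal groups of genes was 0.22 with EnnA, and after a trend with transcript length and expression was removed 16 were higher and 1 lower, with the list call kept. Rplp1 and Rplp0, which form the ribosomal stalk, had log2 changes of 0.88 and 0.81. Of 36 autophagy and lysosome genes, 19 rose and 2 fell (Fisher's exact adjusted p = 0.00253). Sqstm1, encoding the autophagy receptor p62, rose 4.56-fold to 1512 FPKM, and Gabarapl1 and Atg7 rose 1.85-fold and 2.23-fold. Of 25 p53 targets, 13 rose and 3 fell (Fisher's exact adjusted p = 0.0173), among them Gadd45a, Plk2 and Pmaip1 with log2 changes of 1.36 (uncertain, as Gadd45a shares its locus with E230016M11Rik), 1.38 and 1.31. Trp53 rose 2.31-fold, whereas the p53 target Cdkn1a was not called (log2 change -0.11, implied SE 0.15).

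Of 21 genes of ion homeostasis, 11 rose and 2 fell (Fisher's exact adjusted p = 0.0332). They included Itpr2, a calcium release channel (log2 change 1.65), the potassium-chloride cotransporter gene Slc12a4 (1.05) and the osmotic stress factor gene Nfat5 (1.04). Atp2a3, a calcium pump of the endoplasmic reticulum, was higher at a low level, 0.947 FPKM against 0.122 FPKM. Of 12 drug efflux and xenobiotic genes, 9 rose and 1 fell (Fisher's exact adjusted p = 0.00257). The transporter genes Abcb1b and Abcc4 rose 2.23-fold and 2.38-fold. In the NRF2 list 10 of 22 genes rose and 3 fell, and in the metallothionein and zinc list 3 of 6 rose and 2 fell. Neither passed the list test (Fisher's exact adjusted p = 0.139 and 0.383). With a minimum change of 2-fold the NRF2 list (6 members) and the mitochondrial unfolded protein response list (4 members) were called higher. Named members that rose were Hmox1 (log2 change 1.07), the glutathione transferase gene Gsto1 (1.38) and the metallothionein genes Mt1 (1.65) and Mt2 (1.51).

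Cell cycle genes were lower with EnnA. Of 30 genes of G2 phase and mitosis, 24 fell and 0 rose (Fisher's exact adjusted p = 9.48e-09, median log2 change -0.69). Cenpe, a kinetochore motor, was 2.46-fold lower, and the mitotic kinase genes Plk1 and Bub1b were 2.06-fold and 1.99-fold lower. Of 35 DNA replication genes, 20 fell and 2 rose (Fisher's exact adjusted p = 0.000583). Tk1, Rrm2 and Ccne2, which act in nucleotide supply and entry into S phase, were 2.40-fold, 2.30-fold and 2.37-fold lower, with Tk1 and Ccne2 uncertain for shared loci. Of 13 replication-dependent histone genes, 2 were higher and 0 lower, with no list call. Of 23 genes of apoptosis and the BCL2 family, 5 rose and 8 fell, again with no list call (Fisher's exact adjusted p = 1 for higher and 0.648 for lower). The death effector Bok and the initiator caspase gene Casp8 fell (log2 changes -1.28 and -1.26).

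Lipid genes were also lower. Of 24 sterol synthesis and uptake genes, 13 fell and 2 rose (Fisher's exact adjusted p = 0.0156, median log2 change -0.80). The sterol transfer gene Stard4 was 3.06-fold lower, and Acat2, a thiolase gene, was 6.92-fold lower. Of 16 fatty acid synthesis genes, 10 fell and 3 rose (Fisher's exact adjusted p = 0.00941). The desaturase gene Scd2 was 2.67-fold lower and Fasn, fatty acid synthase, was 1.66-fold higher. Of 21 matrix and TGF-beta or SRF target genes, 11 fell and 4 rose (Fisher's exact adjusted p = 0.0352), with Acta2, smooth muscle actin, at a log2 change of -1.95 and the collagen gene Col6a1 at -1.81. Of 20 matrix protease and invasion genes, 11 fell and 1 rose (Fisher's exact adjusted p = 0.0184). The stromelysin gene Mmp3 was 14.6-fold lower and the plasminogen activator gene Plau was 2.94-fold lower.

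Immune genes went both ways with EnnA. Of 26 NF-kB targets, 14 rose and 5 fell (Fisher's exact adjusted p = 0.0104). The iron-binding protein gene Lcn2 rose 5.70-fold, and Tnfaip3 and Nfkbia, feedback inhibitors of the pathway, rose 3.73-fold and 3.46-fold. Of 25 chemokine and cytokine genes, 8 rose and 7 fell, with no list call. Ccl4 and Cxcl10 rose 4.37-fold and 3.88-fold, while Ccl2 (log2 change -0.69, implied SE at most 0.17), Cx3cl1 (-1.70, at most 0.42) and Csf3 (-2.20, at most 0.54) fell. Of 33 interferon-stimulated genes, 8 rose and 14 fell, which did not pass the list test (Fisher's exact adjusted p = 1 for higher and 0.0905 for lower). Among genes of at least 1 FPKM the list was called lower, whereas removing the trend with length and expression left 11 higher and 11 lower and moved the median log2 change from -0.31 to -0.04. Of 18 genes of class I antigen presentation, 8 rose and 4 fell (Fisher's exact adjusted p = 0.166 for higher). Irf1, an interferon-induced transcription factor, rose 4.08-fold, Tap2 rose 2.14-fold and B2m, the light chain of class I molecules, rose with a log2 change of 0.79 (implied SE at most 0.19), in a locus shared with Trim69 that makes it uncertain. The immunoproteasome gene Psmb9 fell (-1.04). Of 5 class II genes, 1 rose and 2 fell: Cd74, the invariant chain, rose from 0.393 to 6.61 FPKM. Cd274, which encodes the checkpoint ligand PD-L1, rose 1.67-fold (log2 change 0.74, implied SE 0.20), and in its list 3 of 15 genes rose and 5 fell. Of 21 mediators of immunogenic cell death, 3 rose and 7 fell. Hmgb1 (log2 change -0.96) and the receptor genes Tlr3 (-1.59) and Tlr4 (-1.63) were among those that fell.

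The cytosolic chaperone genes did not move as a group with EnnA. Of 26 heat shock response genes, 9 rose and 1 fell, where the table as a whole would give 6.31 and 6.48 (Fisher's exact adjusted p = 0.52 for higher and 0.0393 for lower, the latter because few fell). Hspa1b, an inducible Hsp70 gene, rose 6.01-fold, from 0.953 to 5.73 FPKM, and Zfand2a rose 4.44-fold, whereas the constitutive Hsp70 gene Hspa8 was 2.36-fold lower. Hspa1b has a near-identical neighbour, Hspa1a, which neither table lists, so its value is uncertain. The cytosolic HSP90 genes Hsp90aa1 and Hsp90ab1 were not called (log2 changes -0.18 and 0.06, implied SE 0.15 and 0.16), nor were Trap1 (-0.06), Hsf1 (0.10) and Dnajb1 (-0.13). Hsp90b1, the HSP90 form of the endoplasmic reticulum, rose with a log2 change of 0.59 (implied SE 0.17). In the list of HSP90 family and cochaperones 3 of 23 genes rose and 2 fell, and of 32 genes of HSP90 client proteins 7 rose and 9 fell. Among the clients Erbb2 was 2.52-fold lower at 1.19 FPKM (uncertain for a shared locus), and Egfr was 2.18-fold higher.

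**Figure D1:**
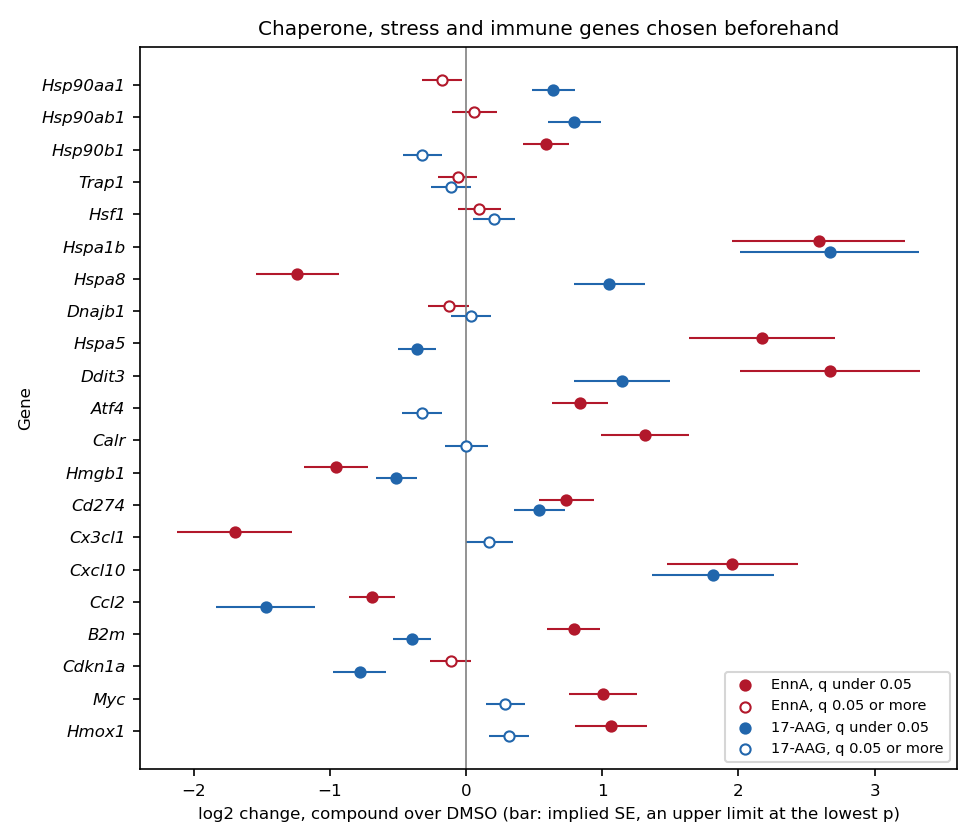
Log2 change over DMSO of 21 chaperone, stress and immune genes fixed beforehand, for EnnA (red) and 17-AAG (blue). Bars show the implied SE, filled points had q under 0.05 in the authors' deposited tables, and Hspa8 stood at -1.24 with EnnA and 1.05 with 17-AAG.

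By the size of the change, the leading genes with EnnA were Car6, a secreted carbonic anhydrase, and Chchd10, a mitochondrial protein. Car6 (mm9 chromosome 4, 149561124 to 149575244 as the authors' deposited table gives the locus) rose from 1.06 to 119.7 FPKM, and Chchd10 (chromosome 10, 75398317 to 75400479) rose 30.9-fold. The snoRNA host transcript Snhg12 rose 10.9-fold in a locus that also lists Snora16a, Snora44 and Snord99, so its value is uncertain. The other risen genes named by size were Angptl6 (10.2-fold, uncertain for a shared locus), the unnamed transcripts 5430416N02Rik, Gm11974 and 1810032O08Rik (10.5-fold, 8.59-fold and 8.38-fold) and the magnesium transporter gene Slc41a3 (8.29-fold). The atypical chemokine receptor gene Cxcr7 (chromosome 1, 92100554 to 92112297) was 20.2-fold lower, from 33.1 to 1.64 FPKM. The natriuretic peptide gene Nppb was 13.8-fold lower, Ly6c1 12.8-fold, Ifi27l2a 9.59-fold, the glutathione transferase gene Mgst3 9.52-fold, Paqr7 9.33-fold, the tubulin gene Tubb4b 7.11-fold and S100a11 7.10-fold.

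In the remaining lists fixed beforehand no call was made with EnnA. Of 30 hypoxia and glycolysis genes 9 rose and 11 fell, of 36 nuclear-encoded OXPHOS genes 4 rose and 3 fell (2 and 15 after the trend was removed), and of 30 proteasome genes 6 rose and 1 fell (3 and 6 after the trend was removed). Of 28 immediate early and MAPK feedback genes 8 rose and 5 fell, with Jund at a log2 change of 1.46 and Dusp6 at -1.59. Of 13 genes of epithelial-mesenchymal transition and stemness 3 rose and 4 fell, with Vim, vimentin, at -1.18. Of the markers of other cell types, 0 of 16 lymphocyte markers and 3 of 15 myeloid markers were listed, and the lysosomal myeloid marker Cd68 rose (1.23) while Lyz2 fell (-0.48). For luminal, basal, endothelial, fibroblast and adipocyte markers, 2, 1, 1, 2 and 0 genes rose and 2, 3, 0, 1 and 1 fell. Adjusted over the list alone, higher calls numbered 24 for the unfolded protein response, 25 for the integrated stress response, 20 for ribosome biogenesis, 28 for ribosomal proteins, 19 for autophagy, 13 for p53, 11 for ion homeostasis, 9 for drug efflux, 15 for NF-kB and 8 for heat shock. Lower calls adjusted over the list alone numbered 27 for mitosis, 22 for replication, 14 for sterols, 10 for fatty acids, 12 for matrix and 11 for proteases. With a minimum change of 2-fold the list calls for mitosis, replication, fatty acids, ribosome biogenesis, ribosomal proteins, autophagy and ion homeostasis were lost, with 2, 5, 2, 5, 0, 2 and 4 members left. The matrix and ion homeostasis calls were also lost among genes of at least 1 FPKM (9 and 10 members), and those for matrix and fatty acids after a trend with transcript length and expression was removed (10 and 8 members), although their medians went only from -0.74 to -0.85 and from -0.42 to -0.34.

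17-AAG raised interferon-stimulated genes, heat shock genes and genes of the extracellular matrix, and lowered sterol synthesis genes, chemokines and MAPK feedback genes. Ifit1, an interferon-induced RNA-binding protein gene, rose 10.5-fold, from 6.19 FPKM with DMSO to 65.2 FPKM with 17-AAG (log2 change 3.40, implied SE at most 0.84). Hsp90ab1 and Hsp90aa1, which encode the cytosolic HSP90 proteins that the compound binds, rose 1.73-fold and 1.56-fold (log2 changes 0.79 and 0.64, implied SE at most 0.20 and 0.16). Csf3, the gene of granulocyte colony-stimulating factor, was 6.86-fold lower. At q under 0.05 in the authors' deposited table, 1760 of 11305 listed genes were higher and 1815 were lower, 31.6% of the genes, and 4682 had an unadjusted p under 0.05. Among genes that also changed at least 2-fold, 469 were higher and 181 lower.

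Of 26 heat shock response genes, 16 rose and 2 fell with 17-AAG (Fisher's exact adjusted p = 1.99e-06, median log2 change 0.53). Hspa1b rose 6.36-fold, from 1.04 to 6.64 FPKM, with the same uncertainty as above, Cryab, a small heat shock protein gene, rose 3.19-fold and the Hsp70 nucleotide exchange factor genes Hsph1 and Hspa4l rose 2.80-fold and 2.09-fold. Hspa8 rose from 1172 to 2432 FPKM (log2 change 1.05, implied SE at most 0.26), and the mitochondrial chaperonin genes Hspd1 and Hspe1 rose 1.55-fold and 1.46-fold. Zfand2a was among those that fell (log2 change -0.50). Hsf1 (log2 change 0.20, implied SE 0.15), Dnajb1 (0.04), Trap1 (-0.11) and Hsp90b1 (-0.32) were not called. In the list of HSP90 family and cochaperones, which shares members with the heat shock list, 5 of 23 genes rose and 3 fell, with no list call. They included the HSP90 activator gene Ahsa1, which rose 1.44-fold, and Fkbp5, which fell (-0.46). Of 33 genes of HSP90 client proteins 8 rose and 3 fell, again with no list call (Fisher's exact adjusted p = 0.497 for higher). Map3k14 rose 2.98-fold and Erbb3 1.80-fold.

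Of 33 interferon-stimulated genes, 28 rose and 1 fell (Fisher's exact adjusted p = 3.42e-16, median log2 change 1.51). The median lay at percentile 100 among random lists of matched expression, whose central 95% ran from -0.15 to 0.20. Oasl1 and the antiviral GTPase genes Mx1 and Mx2 rose 9.57-fold, 7.22-fold and 6.48-fold, the last pair from under 1 FPKM. Rsad2, which encodes viperin, rose 5.69-fold and Cxcl10 rose 3.51-fold. Irf1 rose 2.38-fold and Tap2 1.75-fold, but of 18 class I antigen presentation genes only 4 rose and 2 fell, and B2m (log2 change -0.40, implied SE 0.14) and H2-K1 (-0.65) were lower. Neither lower call was kept after the trend with length and expression was removed (5 higher and 0 lower). Of 5 class II genes 1 rose and 1 fell. Of the immune cell markers, 0 of 16 lymphocyte markers were listed, and of 3 listed myeloid markers 0 rose and 1, Cd68, fell (-1.28). With so few markers listed in a cell line, this had little room to come out otherwise.

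Chemokine, NF-kB and MAPK feedback genes were lower with 17-AAG. Of 27 chemokine and cytokine genes, 12 fell and 5 rose (Fisher's exact adjusted p = 0.00351). Besides Csf3, the chemokine genes Ccl3 and Ccl2 were 4.42-fold and 2.77-fold lower (Ccl2 log2 change -1.47, implied SE at most 0.36), while Cx3cl1 was not called (0.17, 0.17). Of 26 NF-kB targets, 12 fell and 4 rose (Fisher's exact adjusted p = 0.00257), among them the cytokine gene Csf2, 2.71-fold lower. Of 28 immediate early and MAPK feedback genes, 16 fell and 2 rose (Fisher's exact adjusted p = 1.17e-05). Klf2, a zinc-finger transcription factor gene, was 5.03-fold lower, the early response gene Ier3 was 4.40-fold lower and Dusp6, a phosphatase of ERK, was 2.85-fold lower. Of 15 checkpoint and recognition ligand genes 2 rose and 5 fell, with no list call except at a minimum change of 2-fold (3 lower). Cd274 rose 1.45-fold (log2 change 0.54, implied SE 0.19), and Nt5e, the ecto-nucleotidase CD73, and Pvr, a ligand of TIGIT, were 2.45-fold and 2.11-fold lower.

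Of 24 sterol synthesis and uptake genes, 22 fell and 0 rose (Fisher's exact adjusted p = 4.76e-14, median log2 change -0.78). The C4-methylsterol oxidase gene Sc4mol was 2.76-fold lower and the sterol sensor gene Insig1 was 2.41-fold lower. Fdps was 3.47-fold lower, at a level of 3.69 FPKM that pseudogene copies make uncertain. Of 16 fatty acid synthesis genes 2 rose and 1 fell. Of 21 matrix and TGF-beta or SRF target genes, 11 rose and 2 fell (Fisher's exact adjusted p = 0.00104). Myl9, a myosin light chain gene, and Col1a1 rose 8.16-fold and 6.37-fold from under 1 FPKM, and Tgfbi rose 3.34-fold. Of 21 matrix protease and invasion genes, 12 fell and 1 rose (Fisher's exact adjusted p = 0.000267), with Mmp3 4.66-fold lower and Plau 2.17-fold lower.

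Several groups of abundant genes were modestly lower with 17-AAG. Of 36 OXPHOS genes 21 fell, of 30 proteasome genes 20 fell and of 36 cytosolic ribosomal protein genes 14 fell, and 0 rose in any of the 3 lists (Fisher's exact adjusted p = 1.79e-07, 1.58e-08 and 0.00525). The median log2 changes were -0.44, -0.44 and -0.31. Ndufa4, a respiratory chain subunit, and Psma7, a proteasome core subunit, were 1.77-fold and 1.66-fold lower, and Rps23 was 1.58-fold lower. Of 30 genes of mitosis 14 fell, of 35 replication genes 14 fell and of 26 genes of the unfolded protein response 12 fell, and 0 rose in each (Fisher's exact adjusted p = 0.000928, 0.00408 and 0.00257). Cdk1 was 1.52-fold lower, Rrm2 1.70-fold and the transcription factor gene Xbp1 1.74-fold, while Hspa5 fell by 0.36 on the log2 scale (implied SE 0.14). In the 17-AAG table the median log2 change ran from 0.50 in the lowest of 10 equal groups of genes ranked by FPKM to -0.28 in the highest, and from -0.29 in the group with the shortest transcripts to 0.20 in the longest. After this trend with length and expression was removed, 4 OXPHOS, 4 proteasome, 1 ribosomal protein, 4 mitosis, 6 replication and 7 unfolded protein response genes were lower, and none of the 6 list calls was kept. The falls of mitosis, replication and unfolded protein response genes were only partly removed (medians from -0.34 to -0.19, -0.27 to -0.17 and -0.33 to -0.19), and their medians stood at percentiles 0.22, 0.84 and 0.87 among lists matched on length and expression. With a minimum change of 2-fold the same 6 calls were lost, with 2, 0, 1, 0, 0 and 1 members left.

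**Figure D2:**
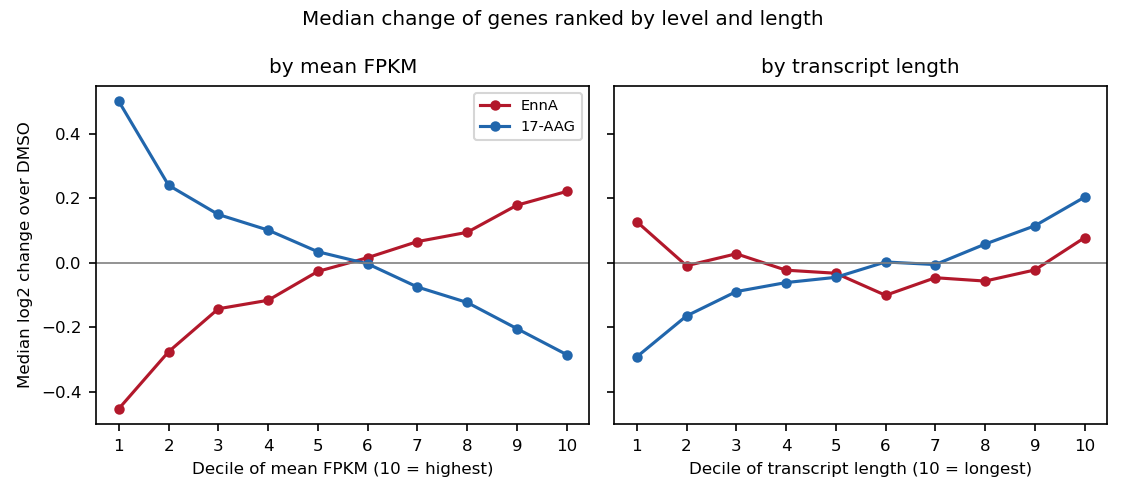
Median log2 change over DMSO (vertical axis) of genes in 10 equal groups ranked by mean FPKM (left) or by transcript length (right), for EnnA (red) and 17-AAG (blue). With 17-AAG the median fell from 0.50 to -0.28 as expression rose, and with EnnA it ran the other way, from -0.45 to 0.22.

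By the size of the change, the leading risen genes with 17-AAG were Vdr, the vitamin D receptor (mm9 chromosome 15, 97684857 to 97738727 as the authors' deposited table gives the locus), 11.6-fold higher at 12.1 FPKM, and Ifit1 (chromosome 19, 34715378 to 34724499). They were followed by Oasl1, Tmem140 (7.31-fold, in a locus shared with 3110062M04Rik), the apolipoprotein L genes Apol9a and Apol9b (6.91-fold and 6.19-fold, close paralogs whose reads may be split), Hspa1b, Lrrc15 (5.77-fold), Rsad2 and Angptl4, an inhibitor of lipoprotein lipase (5.62-fold). The largest fall was that of Rpl27 (chromosome 11, 101303558 to 101306910), 8.51-fold lower at 3.55 FPKM. The other ribosomal protein genes named by size were Rpl11, Rps23 and Rpl10a, with log2 changes of -0.81, -0.66 and -0.59, and Rpl27 has many pseudogene copies, so its value is uncertain. Fabp4, a fatty acid-binding protein gene, and S100a8, a subunit of calprotectin, were 8.48-fold and 8.47-fold lower. The adaptor gene Lat2 was 6.43-fold lower, Tm4sf1 4.88-fold and the respiratory chain gene Cox5b 4.48-fold, the last also with pseudogene copies.

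Stress genes raised by EnnA responded less evenly to 17-AAG. Of 30 genes of the integrated stress response 8 rose and 6 fell, with no list call (Fisher's exact adjusted p = 0.319 for higher). After the trend with length and expression was removed, 9 were higher and 2 lower, and the list was called higher. Ddit3 rose 2.21-fold (log2 change 1.15, implied SE 0.35), Ppp1r15a rose 1.68-fold, and Atf4 was not called (-0.32, 0.15). Of 25 p53 targets 5 rose and 4 fell, and Cdkn1a was 1.72-fold lower. Myc (log2 change 0.29, implied SE 0.15), Hmox1 (0.32, 0.15) and Calr (0.00, 0.16) were not called, and Hmgb1 fell (-0.51, 0.15). No list call was made for NRF2 (3 of 22 rose, 5 fell), apoptosis (2 of 23, 7), mitochondrial unfolded protein response (3 of 14, 3), ribosome biogenesis (3 of 27, 3), autophagy (4 of 36, 6), hypoxia (4 of 30, 5), ion homeostasis (5 of 20, 5), metallothioneins (0 of 6, 2), drug efflux (1 of 11, 3), histones (2 of 18, 0), immunogenic cell death (2 of 21, 5) or epithelial-mesenchymal transition (2 of 13, 4). After the trend was removed NRF2 had 5 higher and 2 lower, hypoxia 6 and 2 and the mitochondrial list 4 and 1. Apoptosis still had more lower genes (3 and 6), and none of these 4 lists was called. Without that correction, for luminal, basal, endothelial, fibroblast and adipocyte markers 2, 0, 0, 2 and 0 genes rose and 1, 1, 0, 0 and 1 fell. Adjusted over the list alone, higher calls numbered 18 for heat shock, 28 for interferon-stimulated genes and 12 for matrix. Lower calls adjusted over the list alone numbered 22 for sterols, 13 for chemokines, 12 for NF-kB, 18 for MAPK feedback, 12 for proteases, 23 for OXPHOS, 22 for the proteasome, 16 for ribosomal proteins, 16 for mitosis, 15 for replication and 15 for the unfolded protein response.

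**Figure D3:**
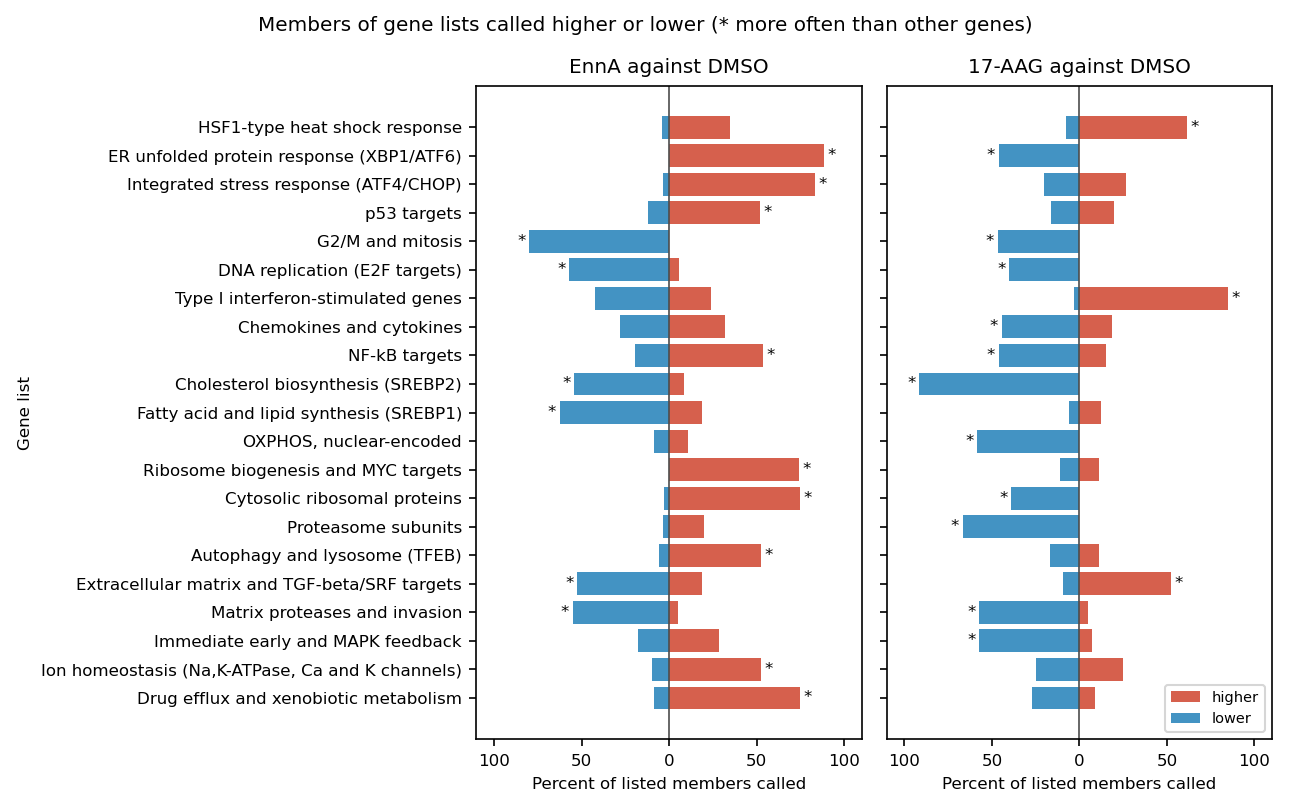
Percent of listed members of each gene list called higher (red, right) or lower (blue, left) against DMSO, for EnnA (left panel) and 17-AAG (right panel), over the lists called for at least 1 compound. Asterisks mark lists called more often than other genes at an adjusted Fisher's exact p under 0.05, such as interferon-stimulated genes with 28 of 33 members higher with 17-AAG.

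Set against each other, the compounds differed in lists that include the unfolded protein response, the integrated stress response, interferon-stimulated genes and matrix genes. Hspa5 rose 4.51-fold with EnnA and fell with 17-AAG, a difference in log2 change of 2.53 (SE 0.55). Its fall with 17-AAG, 0.36 on the log2 scale, was close to the median of -0.28 of the most abundant of 10 equal groups of genes. Hspa8 went the opposite way, with a difference of -2.29 (SE 0.40). The chaperone targets of 17-AAG also differed: Hsp90aa1 by -0.82 (SE 0.22) and Hsp90ab1 by -0.73 (SE 0.25). Ifit1 rose less with EnnA than with 17-AAG, by -2.59 (SE 0.86), and all 5 of these differences were called. The SE of a difference is an upper limit wherever p was at its lowest with either compound, as for these 5 genes. The question of whether the compounds act alike on the transcriptome follows from the series' design, but their structures are unrelated and their doses, 7.4 and 0.5 µM, are not matched. Of 10922 genes with a value in both tables, 4169 differed at a Benjamini-Hochberg adjusted p under 0.05 by a z test of the difference, 2110 with the EnnA effect above and 2059 with it below. At an unadjusted p under 0.05 there were 5080, centring gave 1867 above and 2264 below, and errors inflated 1.5 times left 869 in all. The tables were normalized separately, and the authors' DMSO values differ between them by a constant 1.10-fold, which cancels in the changes over DMSO.

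Of 26 unfolded protein response genes, 22 had the EnnA effect above that of 17-AAG and 0 below (Fisher's exact adjusted p = 3.18e-11). Called members included Vimp (2.64, SE 0.52) and Manf (2.16, SE 0.40). The counts were 21 above and 2 below of 30 for the integrated stress response (4.35e-08), 30 above and 0 below of 36 for ribosomal proteins (1.47e-14) and 16 above and 0 below of 27 for ribosome biogenesis (8.45e-05), with the Fisher's exact adjusted p in brackets. After each compound's trend with length and expression was removed, 7 ribosomal protein and 6 ribosome biogenesis genes were above. The median differences went from 0.87 to 0.23 and from 0.62 to 0.39, and neither list call was kept. For MAPK feedback 16 of 28 were above and 2 below (0.000135), and for drug efflux 8 of 11 above and 2 below (0.00181), again with the exact adjusted p. Of 33 interferon-stimulated genes, 26 had the EnnA effect below that of 17-AAG and 1 above (Fisher's exact adjusted p = 5.42e-12), and 12 fell with EnnA and rose with 17-AAG. Ifi27l2a, for example, was 9.59-fold lower with EnnA and 1.64-fold higher with 17-AAG. Of 21 matrix genes 13 were below and 3 above (Fisher's exact adjusted p = 0.000186), with Col6a1 at -1.81 with EnnA and 0.92 with 17-AAG. The EnnA effect was also above in the lists of p53 targets (12 of 25, 0.00737), autophagy (16 of 36, 0.00448), NRF2 (10 of 22, 0.0235), NF-kB (11 of 26, 0.037), OXPHOS (14 of 36, 0.0247) and the proteasome (13 of 30, 0.0203), with the exact adjusted p. For NRF2, OXPHOS and the proteasome the median difference was that of other genes of like expression (percentiles 49.7, 25.2 and 57.3 among matched random lists), and after trend removal these 3 list calls and that for autophagy were not kept (6, 2, 2 and 7 members). Cd68 and Csf2 were among the single genes that rose with EnnA and fell with 17-AAG. Lists of mitosis (0 above, 8 below of 30) and replication (2 above, 6 below of 35) were not called below (Fisher's exact adjusted p = 0.476 and 1), although their median differences of -0.36 and -0.20 stood at percentiles 0 and 0.07 among matched random lists. With the trend removed 14 mitosis genes were below and that list was called, while replication with 10 below was not. Sterol genes showed no list difference, with 7 of 24 above and 1 below (Fisher's exact adjusted p = 0.437 and 0.206), and 13 of them fell with both compounds. In the heat shock list 4 of 26 genes were above and 7 below, with no list call (Fisher's exact adjusted p = 0.569 for below), although the median difference of -0.23 stood at percentile 0 among matched random lists. For the HSP90 family and cochaperones, with 3 of 23 above and 5 below, the percentile was 0.89. With the trend removed 12 heat shock genes and 9 of the HSP90 family were below, and both lists were called, as was hypoxia and glycolysis (13 of 30). Hspa1b differed by -0.08. Its SE is at most 0.92, since p was at its lowest with both compounds. That limit is too wide to tell a shared from a different change.

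**Figure D4:**
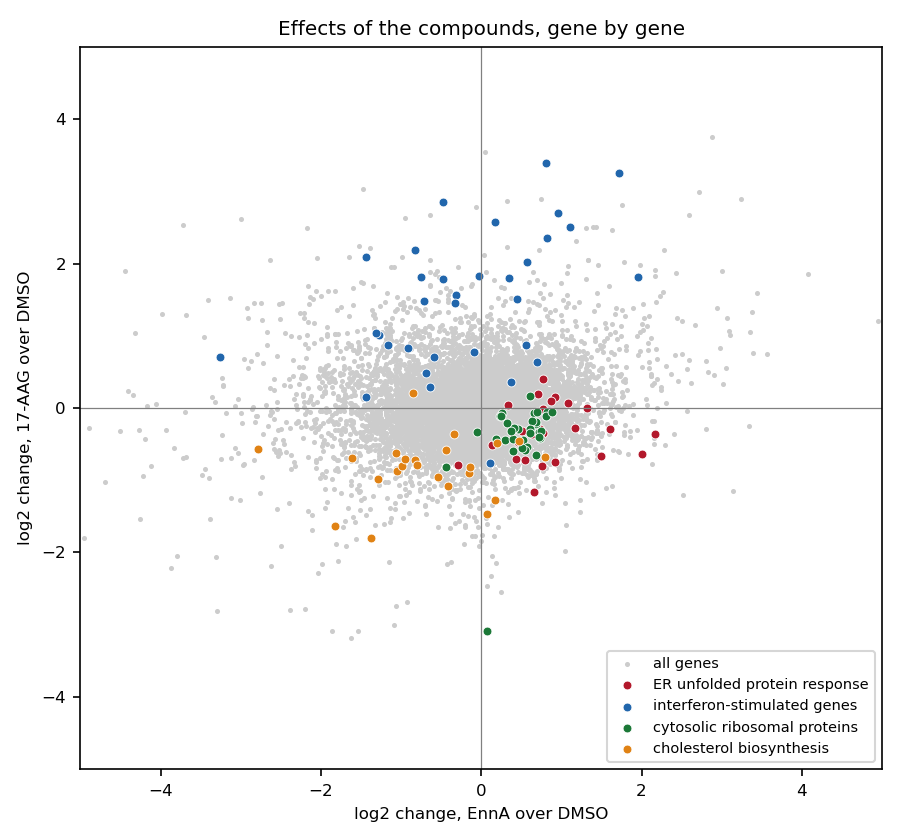
Log2 change over DMSO with EnnA (horizontal axis) and with 17-AAG (vertical axis) for genes in both tables; 11 genes lie outside the axes, which end at 5. Unfolded protein response genes (red) and ribosomal proteins (green) lie to the right, interferon-stimulated genes (blue) at the top, and sterol genes (orange) mostly at the lower left.

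Among genes above the expression floor, the widest differences with EnnA above, all called and given with their SE, were those of Car6 (6.86, 1.70), Il23a (4.28, 0.84), Chchd10 (3.75, 1.26), Lcn2 (3.72, 0.69), Rpl27 (3.16, 0.79), Slc7a3 (3.10, 0.71), Ccl4 (2.90, 0.59), Ppp1r15a (2.82, 0.90), Ankrd33b (2.77, 0.62) and the glucocorticoid-induced gene Tsc22d3 (2.71, 0.48). Those with EnnA below, also all called, were Cxcr7 (-4.52, 1.08), Ifi27l2a (-3.97, 0.91), Apol9b (-3.58, 0.71), Paqr7 (-3.54, 0.81), Sept4 (-3.45, 0.63), S100a4 (-3.27, 1.07), Akap12 (-3.26, 0.57), Tgfbi (-3.24, 0.57), Ly6c1 (-3.01, 0.92) and Samd9l (-2.99, 0.56). Il23a and Lcn2 rose with EnnA and fell with 17-AAG (log2 changes -1.14 and -1.21), while Sept4, Akap12, Olfml3 and Wdr6 fell with EnnA and rose with 17-AAG (1.24, 1.66, 0.99 and 1.03). Wdr6 shares its locus with another listed gene, so its value is uncertain.

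Both compounds changed 1889 of these genes, 1078 in the same direction (57.1%) and 811 in opposite directions. Shared genes included Ddit3, Irf1, Cxcl10 and Cd274, which rose with both, and Mmp3, S100a8, Dusp6 and Hmgb1, which fell with both. In all, 491 genes rose with both and 587 fell with both, where independent lists would share 382 and 455. The differences of Ddit3 (1.53, SE at most 0.75) and Cxcl10 (0.14, SE at most 0.66) were not called. Because these SEs are upper limits, that does not show that the changes were alike. Another 391 rose with EnnA and fell with 17-AAG, and 420 did the reverse, against 435 and 400, but among genes of at least 1 FPKM the reverse group held 279 against 304. Across genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.48 and a Spearman rho of 0.08. The Pearson r was 0.17 without the microRNA gene Mir546, an extreme value in both tables, so it rests on that gene. With no effect at all, the shared DMSO libraries alone gave a simulated r of 0.44 and rho of 0.44, and a simulated same sign in 65.6% of genes against 51.9% observed. The simulated tables held error alone, while the data also hold effects of each compound. Observed r, rho and share of same sign therefore cannot be read as agreement above or below these values. The covariance without Mir546 was 0.0734 against a simulated 0.0156. The DMSO libraries could not be split, so part of the shared calls may come from them.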

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

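The tests of immune cell RNA, of reads shared within gene families and of a level-dependent shift, and the correction for transcript length and expression (also of the difference), were chosen only after the result was seen. The lists of snoRNA hosts and decay factors were also chosen after their values were seen. In 14 gene lists the compounds' effects against DMSO differed by a test of the difference. The EnnA effect was above the 17-AAG effect for 22 unfolded protein response genes, 21 integrated stress response genes, 16 ribosome biogenesis genes, 30 ribosomal protein genes, 16 immediate early and MAPK feedback genes, 8 drug efflux genes, 12 p53 targets, 16 autophagy genes, 11 NF-kB targets, 10 NRF2 genes, 14 OXPHOS genes and 13 proteasome genes. It was below for 26 interferon-stimulated genes and 13 matrix genes. For NRF2, OXPHOS and proteasome genes the median difference stood at percentiles 49.72, 25.21 and 57.31 among random lists of matched expression, so these lists differed no more than other genes of like level. With the trend in length and expression removed from both compounds, 8 of the 14 list calls were kept, and those for ribosomal proteins, ribosome biogenesis, autophagy, NRF2, OXPHOS and the proteasome were not. The ribosomal protein median went from 0.87 (quartiles 0.68 and 1.05) to 0.23 (-0.02 and 0.40), so the call ended because the difference itself shrank. The subtracted medians included these genes, so a real shared difference would be partly removed too. The doses, 7.4 and 0.5 µM, were not matched, so a difference in dose stays open for each of these lists.

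OXPHOS, proteasome and ribosomal protein genes were lower with 17-AAG, with a median log2 change of -0.38 over 102 genes. Against transcript length, the median stood at percentile 10.17 among random lists matched on length and expression (random median -0.33, central 95% from -0.41 to -0.25), but the lists stood apart, at percentile 85.88 for ribosomal proteins, 4.69 for OXPHOS and 1.34 for the proteasome (median -0.44, random central 95% from -0.42 to -0.16), so a bias with length and level may account for the ribosomal protein fall and for part of the others. Random lists matched on GC content and expression all lay above this median (percentile 0). A single scaling factor would move all genes alike, but the median of expressed genes was only -0.03, and centring on it left -0.35. Among lists matched on expression alone, the ribosomal proteins did not stand apart (percentile 19.46), while OXPHOS and proteasome genes lay lower (percentiles 0.52 and 0.48). For ribosomal proteins this cannot tell a shift tied to expression level from a real fall of abundant genes. Removing the trend moved the medians from -0.44 (quartiles -0.60 and -0.29) to -0.05 (-0.23 and 0.01) for OXPHOS, from -0.44 (-0.53 and -0.29) to -0.10 (-0.28 and 0.02) for the proteasome and from -0.31 (-0.44 and -0.16) to 0.12 (-0.12 and 0.23) for ribosomal proteins, and the calls ended because the changes themselves shrank. The subtracted medians included these genes, so a real shared fall would be partly removed too. The shrinkage therefore cannot tell such a fall from a bias.

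Interferon-stimulated genes were higher with 17-AAG, 28 of 33. Transcript length (percentile 100) and GC content (percentile 100) matched random lists did not reach their median. RNA of immune cells would bring immune cell markers, and 0 of 31 were listed and higher, with 3 listed. In a cell line with so few markers listed, this test had little room to come out otherwise. Reads shared within gene families would leave the other members flat, and the 19 members outside the Ifit, Ifitm, Oas, Mx, Ifi27, Ifi44 and Trim30 families had a median log2 change of 1.01. An interferon-like response to 17-AAG at this dose is therefore a candidate explanation, as a hypothesis found and tested on the same data, with the source of the signal untested.

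Non-coding snoRNA host genes were higher with EnnA for 6 of 11 and lower for 2, which did not pass the list test (Fisher's exact adjusted p = 0.0845). Random lists matched on length and expression did not reach the median of the 9 hosts with a length (percentile 100). The list was chosen after its values were seen, so a high percentile was likely beforehand. It is weak evidence against a bias with transcript length. Reads of the snoRNAs inside the hosts cannot be told apart from a rise of the hosts: the 7 hosts with no snoRNA listed had a median of 1.23, but ranged from -1.14 to 2.57. Less nonsense-mediated decay, which degrades many such hosts, may contribute, since 6 of 8 decay factors under feedback by that pathway rose. With 17-AAG, however, 5 of 11 hosts rose and 0 fell while only 2 of 8 decay factors rose. Less decay was not tested on the hosts themselves.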

How the results depend on the processing

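The alternatives without shared loci and small RNA genes, with a lower limit on the errors, without Mir546, and with the length and expression trend removed were chosen only after seeing the data. No paired analysis was possible because the tables hold 1 pooled value per group. Not run were leaving out each replicate in turn, a replicate block, other count tools, another pseudocount per library and p from the authors' test statistic, since the tables hold no values per library and no statistic.

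With a minimum of 2-fold, calls came to 1561 for EnnA (605 higher, 956 lower) and 650 for 17-AAG (469, 181), and with a pseudocount as well to 917 (430, 487) and 261 (157, 104); both leave fewer genes by construction. At q under 0.01, 17-AAG had 2279 (1105, 1174), and the overlap was 261 both higher, 346 both lower and 416 opposite. Errors inflated 1.5 times left 869 differences (412 above, 457 below). Pearson r was 0.14 at 1 FPKM or more and 0.17 without Mir546. With a minimum of 2-fold, 19 list calls were made against 29. Beyond the stricter thresholds, the cause was not tested.

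Counts stayed within 1.5 times under the other alternatives: EnnA 4234 to 5422, 17-AAG 2528 to 3575, differences 3348 to 4131 (1867 above and 2264 below on centring), list calls 22 to 29. Centring turned the sign of 0 calls against DMSO. It left q as it was and used medians of only 0.017 (EnnA) and -0.032 (17-AAG), so this outcome was all but fixed. Removing the trend kept 4354 of 5422 EnnA calls and 1939 of 3575 17-AAG calls, and 0 had the opposite sign; of 4137 differences among genes with a length, 2466 were kept and 0 turned. All 29 list calls were kept on centring, which follows from the unchanged q and signs and is no test of them. Of the 29, 27 were kept at 1 FPKM or more, 16 at 2-fold and 21 after the trend was removed. The calls lost there had adjusted p from 0.0758 to 1. With the pseudocount 470 named gene values stayed within their error, 62 moved and 0 reversed. Depth is unknown; under 2 FPKM the median implied error was 0.366 with EnnA and 0.344 with 17-AAG, so modest changes of weakly expressed genes were not resolved.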

Other observations

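The lists of tubulins, S100 proteins, iron genes, snoRNA hosts and decay factors were all chosen only after the data were seen, and their Fisher's exact p was adjusted over 20 tests. Tubulin genes were lower with both compounds. With EnnA 11 of 11 fell (Fisher's exact adjusted p = 4.53e-06, median log2 change -1.65), from Tubb4b (-2.83), Tubb3 (-2.57) and Tuba1a (-2.06) to Tubb5 (-1.19) and the gamma-tubulin gene Tubg1 (-0.41). With 17-AAG 8 of 11 fell and Tubb2b rose (Fisher's exact adjusted p = 0.000454, median -0.51; Tubb2b 0.45, Tubb6 -0.86). Tubulin paralogs are close in sequence, so the values of single members are uncertain. Of 8 listed S100 genes, which encode small calcium-binding proteins, 7 fell with EnnA (Fisher's exact adjusted p = 0.00186, median -1.74) and 6 with 17-AAG (0.00186, -0.80). S100a4 (-4.22), S100a11 (-2.83) and S100a6 (-2.37) led with EnnA, and S100a8 (-3.08), S100a10 (-1.07) and S100a13 (-1.07) with 17-AAG. For the tubulin and S100 lists the trend with transcript length and expression was neither removed nor matched. With 17-AAG the median log2 change was -0.28 in the most abundant and -0.29 in the shortest of 10 equal groups of genes. How much of the 17-AAG falls follows that trend is therefore unknown.

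Of 6 iron storage and import genes, 4 rose and 1 fell with EnnA, which did not pass the list test (Fisher's exact adjusted p = 0.0845, median 1.30). The ferritin genes Ftl1 (1.67) and Fth1 (1.39) and the transferrin receptor gene Tfrc (2.12) rose; ferritin genes have pseudogene copies, so their values are uncertain. With 17-AAG 2 rose and 1 fell (Fisher's exact adjusted p = 0.364), with Tfrc at 0.97. Among the snoRNA hosts Snhg5 (2.57), Gas5 (1.45) and Snhg6 (1.23) rose with EnnA and Snhg3 (-0.87) and Snhg4 (-1.14) fell. Snhg1 rose too (2.98), but its locus also lists a snoRNA, so its values with both compounds are uncertain. With 17-AAG 5 of 11 hosts rose and 0 fell (Fisher's exact adjusted p = 0.0616, median 0.52), with Snhg1 at 0.84. Of 8 decay factors, 6 rose with EnnA (Fisher's exact adjusted p = 0.0143, median 0.68), among them Upf2 (0.89) and Smg5 (0.82), and 2 with 17-AAG (0.493, 0.28).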
